A study of Mus musculus with 3 samples.

How the data were processed

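Gene expression was compared between multipotent progenitors (MPPs) labelled Mef2c-deficient and MPPs of control mice on 3 mouse 2-colour Agilent arrays. The cells called MPPs were bone marrow cells without lineage markers that carried c-kit and Sca-1. This gate as stated names no marker that sets stem cells apart. Per the labels, 15000 cells per sample were sorted after lineage depletion, 2 days after the last of 4 daily injections of 250 µg poly(I:C), an RNA analog that switches on the Mx1-Cre recombinase. The lineage antibodies recognised B220, Ter119, Gr-1, Mac-1 and CD3. Mutant mice carried Mx1-Cre with floxed Mef2c alleles, and controls carried the floxed alleles without Cre. An effect of Cre itself therefore cannot be separated from the loss of Mef2c.

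Per the labels' protocols, mRNA was isolated on magnetic beads and amplified by a global PCR of its cDNA (SuperAmp), and 250 ng of cDNA was labelled. Mutant cDNA carried Cy3 and control cDNA Cy5 on each of the 3 arrays. The labels give no dye swap, so as labelled a dye effect cannot be separated from the genotype. All 3 arrays lay on 1 slide, per the file headers, so a slide block could not be fitted.

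The authors' scanner files hold spot intensity values on a linear scale, made with Agilent Feature Extraction 9.5.1.1, per the file headers. Mean foreground and median local background intensities were used as deposited. The same files hold processed signals, which were background-subtracted and dye-normalized by Feature Extraction per the file headers, and a log10 ratio of Cy5 over Cy3 per the file headers. A deposited table holds the authors' log2 ratio of each spot, and the submitters' processing notes name limma with no version. How those ratios were normalized is not given in the sources used here.

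The direction of the deposited log2 ratios was checked against the scanner's ratio of Cy5 over Cy3. Across spots the correlation was -0.947 on array 1, 0.935 on array 2 and -0.939 on array 3, so the deposited column of array 2 runs opposite to the other 2 although the labels give the same dyes. Whether array 2 was a dye swap or only its column was turned is not known, and if it was a swap the labelled ratios of that array have the wrong sign. The columns' medians were -0.0148, 0.0129 and -0.00249. Each column had 201 empty rows, at places that differed between columns, so filled rows were matched to spots in order within each column. The weakest correlation in any block of 1000 spots was 0.923 in size. The deposited values served as an alternative only.

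Background was corrected with limma's normexp (offset 50) and each array was normalized by loess, with control spots at a weight of 0 and then left out. Spots flagged as outliers were left out, 300, 331 and 252 on arrays 1, 2 and 3. Ratios were expressed as log2 of mutant over control. Signals of single channels, given below as levels of a library, were also normalized between arrays by limma's Aquantile, which leaves the ratios unchanged. Of 41174 probes, 32909 were well above background in the same channel on at least 2 arrays and measured on at least 2. Probes took current symbols through RefSeq accessions (23075 probes), through the symbol (6582) or through a synonym (3077), and 8440 kept the name in the file. Each gene was represented by its probe with the highest mean log2 intensity, which left 22221 genes.

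Ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only), with Benjamini-Hochberg adjustment at 0.05. Before the data were examined, 17 gene lists were fixed. They were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. With an estimated correlation, the test takes its degrees of freedom from the 3 arrays, so a call lost there need not mean correlated genes. The fry test was also run: its directional p tests whether a list's genes move, on balance, one way, and its mixed p whether they change in either direction, and neither compares a list with other genes. The rule for named genes was fixed at the same time. It took Mef2c, then in each direction up to 12 genes that passed and ran the same way on all 3 arrays. Where fewer than 5 passed, it was filled to 5 by unadjusted p and these are said not to pass. Clone identifiers, and probes not well above background in both channels on every array, were left out of that part. Of each list it took up to 4 called members, or the 2 largest where fewer than 2 were called. Further genes named outside the rule were chosen after their values were seen, and are marked so.

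The tests were checked on simulated ratios with the spread of the real arrays, in which a seeded set of 200 of 22221 genes were changed. At an adjusted p under 0.05 the Mef2c-deficient against control fit recovered 1 of 67 genes changed 2-fold, 32 of 67 changed 4-fold and 63 of 66 changed 16-fold, with 2 false calls. In a simulation of 22221 genes without the 16-fold changes, it recovered 0 of 100 changed 2-fold and 0 of 100 changed 4-fold, of which 78 and 99 had an unadjusted p under 0.05. Recovery at an adjusted p thus depended on how many large changes were present. Of unchanged genes, 5.22% had an unadjusted p under 0.05. Camera called a simulated list of 32 genes shifted by 0.50 on the log2 scale and called 0 of the 17 lists without a shift. The simulated genes were independent of each other. The simulation thus cannot show how often camera calls an unshifted list of correlated genes, and the real immediate early list had an estimated correlation of 0.928.

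Alternatives changed the background correction, the normalization within and between arrays, the filter on dim probes, the outlier flags, the choice of probe, the empirical Bayes settings, the array weights, the source of the values and the pairing of channels, and left out each array in turn. Turning array 2, using the deposited signs and leaving out background correction and loess together were added after seeing the data. The number of arrays limits the precision.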

Results

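Expression was measured in MPPs, the early blood progenitors that give rise to lymphoid and myeloid cells, from Mef2c-deficient and control mice. Mef2c is a transcription factor, and the series asks about its part in the choice between lymphoid and myeloid fates. Each of 3 arrays carried 1 mutant and 1 control sample. The labels do not say whether the replicates came from separate animals, so p-values measure only the spread between these samples. Between 73.4% and 80.4% of probes were well above background in a channel, and no spot was saturated.

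In Mef2c-deficient MPPs the genes with the smallest p-values on the low side included Tcf7 and Gata3, transcription factors of T cell development, and those on the high side included Kmo, an enzyme of tryptophan breakdown, and the lysosomal protease Ctsh. Signed values follow the labels, with mutant in Cy3 on every array, whereas the deposited ratios of array 2 run opposite to those of the other 2 arrays. The log2 ratio of Tcf7 was -1.86 ± 0.26 (SD, n = 3) and that of Gata3 was -1.39 ± 0.17. Cmah, which hydroxylates sialic acid, had a log2 ratio of -2.32 ± 0.30, the kinase gene Nuak1 -1.64 ± 0.34 and the focal adhesion gene Tns1 -1.54 ± 0.38. On the high side the log2 ratio was 1.83 ± 0.33 for Kmo, 1.76 ± 0.34 for Ctsh, 1.59 ± 0.18 for the zinc finger gene Zfp318, 1.71 ± 0.37 for coagulation factor F10 and 1.69 ± 0.47 for the C-type lectin receptor gene Clec4a2. As labelled, each of these 10 genes ran the same way on all 3 arrays, which the rule that chose them required, and none of them passed the test over all genes (adjusted p = 0.461). With array 2 turned, which by construction ends that agreement, Tcf7 was at -0.42 ± 2.24 and Kmo at 0.46 ± 2.20.

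By limma, 0 of 22221 genes had an adjusted p under 0.05. At an unadjusted p under 0.05 there were 2251 genes, 1069 higher and 1182 lower in the mutant, where chance gives 1111. With median centring in place of loess this split was 552 higher and 2318 lower, and with the scanner's processed signals 695 and 1550. With array 2 turned it was 335 and 308, of which 12 were among the 2251, and without array 1 it was 638 and 662. As labelled, 676 of the 2251 genes had another kept probe. For 77.4% of these the mean of the other probes had the same sign, where chance gives 50%. Among genes measured on all 3 arrays, 7882 (35.5%) ran the same way on all 3 as labelled, with 3374 higher and 4508 lower, and 4462 (20.1%) with array 2 turned, with 2366 higher and 2096 lower, where chance gives 25%. Each labelled ratio is of Cy3 over Cy5, so a dye bias of single genes would raise this agreement as labelled and lower it with array 2 turned. It would also add to the 2251 genes, and neither count settles the direction of array 2.

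**Figure D1:**
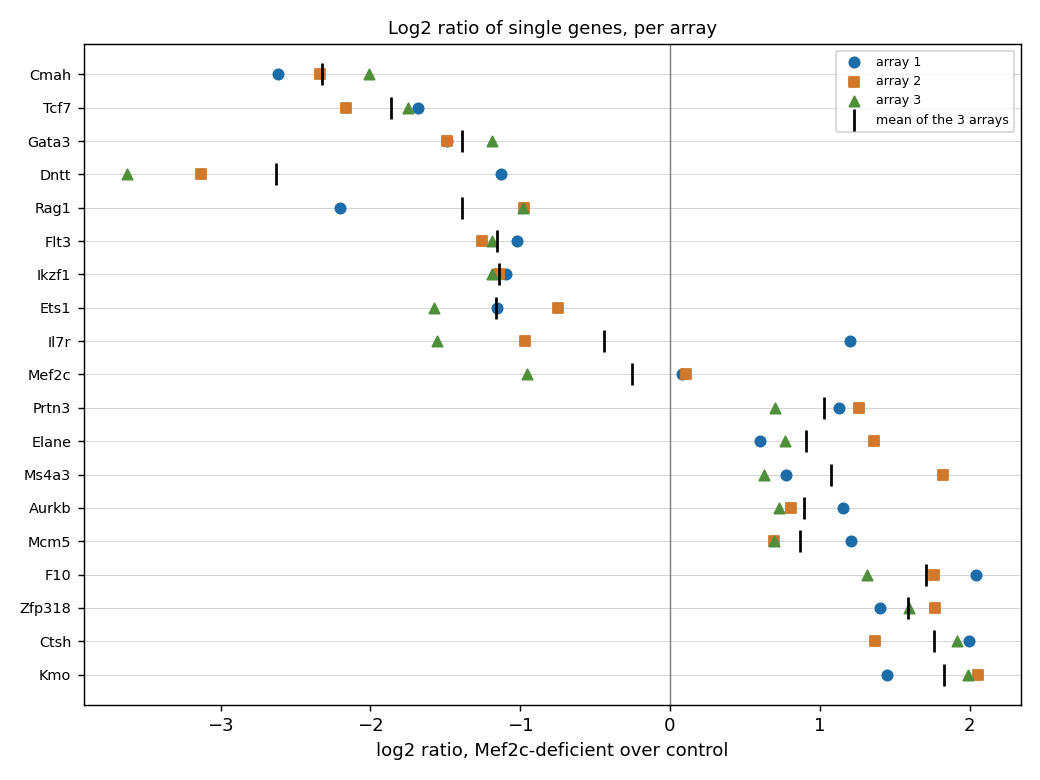
Log2 ratio of mutant over control (x axis) of 19 genes (y axis) on each of the 3 arrays, with the mean as a bar. Tcf7, Gata3 and Flt3 lie below 0 and Kmo, Ctsh and Prtn3 above 0 on all 3 arrays, while Il7r and Mef2c lie on both sides. Flt3, Ikzf1, Ets1, Il7r, Prtn3, Elane and Ms4a3 were chosen after their values were seen.

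Mef2c itself was measured by 2 probes, which gave no common direction. The tested probe, for NM_025282, had log2 ratios of 0.08, 0.10 and -0.96 on arrays 1, 2 and 3, with a mean of -0.26 ± 0.61 (SD, n = 3). Its adjusted p by limma was 0.741. The dimmer probe, for AK044643, had a mean of 0.52 ± 0.48 and was well above background in 2 mutant and 1 control samples, so it also passed the filter without being tested. Without array 3 the tested probe's mean was 0.09, and with the mean of both probes it was 0.13. The labels do not say which part of the gene was floxed, so a probe outside that part checks nothing about the labels. The loss of Mef2c in these samples thus rests on the labels and was not verified by these probes.

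Genes of early lymphoid priming fell in Mef2c-deficient MPPs as a list (camera, adjusted p = 0.000452; adjusted p = 0.523 with an estimated correlation). The list's mean log2 ratio was -0.60 over 19 measured genes, with -0.44, -0.74 and -0.62 on arrays 1, 2 and 3. Of these genes 15 lay below 0 and 9 ran low on all 3 arrays. As labelled, the largest differences were in Dntt, which adds nucleotides at antigen receptor joins, at -2.63 ± 1.32 (SD, n = 3), and in the recombinase gene Rag1, at -1.39 ± 0.70. The other probes of these genes had means of -2.21 for Dntt and -0.44 for Rag1, and turning array 2 gave the tested probes means of -0.54 for Dntt and -0.74 for Rag1. Over all genes 0 members were called by limma, with 7 lower at an unadjusted p under 0.05, and 5 were lower when adjusted over the list alone: Dntt, Rag1, Ikzf1, Flt3 and Ets1, the last 3 named after their values were seen. The cytokine receptor gene Flt3 had log2 ratios of -1.02, -1.26 and -1.19 on the 3 arrays, and Ikzf1, the gene of the lymphoid regulator Ikaros, had -1.09, -1.14 and -1.19. The interleukin 7 receptor gene Il7r, also named after its values were seen, had 1.20, -0.97 and -1.56. Its probe was dim, well above background in only 1 mutant and 2 control samples. With array 2 turned, the list's mean was -0.11 and the call was lost (adjusted p = 0.920).

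The T and NK lineage list also fell, with a mean log2 ratio of -0.38 over 21 genes (camera, adjusted p = 0.00405; adjusted p = 0.523 with an estimated correlation). Its mean was -0.34, -0.48 and -0.32 on arrays 1, 2 and 3, and 18 members lay below 0. Tcf7 and Gata3 were the 2 members that were lower when adjusted over the list alone, against 0 over all genes by limma, where 4 were lower at an unadjusted p under 0.05. With array 2 turned the mean was -0.06 and the call was lost (adjusted p = 0.920). The B lineage list did not pass (adjusted p = 0.198), with a mean of -0.19 over 17 genes. Its members Cd24a and Cd72 had log2 ratios of -0.78 ± 0.03 and -0.65 ± 0.32 (SD, n = 3) and did not pass over all genes or over the list alone.

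Cell cycle genes rose as a list, with a mean log2 ratio of 0.35 over 32 genes (camera, adjusted p = 1.57e-06; adjusted p = 0.523 with an estimated correlation). The mean was 0.50, 0.27 and 0.29 on arrays 1, 2 and 3, and 26 members lay above 0. The mitotic kinase gene Aurkb had a log2 ratio of 0.90 ± 0.22 (SD, n = 3) and Mcm5, of the replicative helicase, 0.87 ± 0.30. The proliferation marker Mki67, named after its values were seen, had -0.24 ± 0.26. Called members numbered 0 both over all genes and adjusted over the list alone, where 8 members were higher and 0 lower at an unadjusted p under 0.05 by limma. With array 2 turned the list's mean was 0.17, with an adjusted p of 0.0187 (adjusted p = 0.969 with an estimated correlation).

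Ribosomal protein genes fell as a list, with a mean log2 ratio of -0.31 over 24 genes (camera, adjusted p = 0.00118; adjusted p = 0.523 with an estimated correlation). Means on arrays 1, 2 and 3 were -0.15, -0.46 and -0.33, and 22 members lay below 0. Rps24 had -0.84 ± 0.55 and Rps18 -0.74 ± 0.54 (SD, n = 3), and with array 2 turned Rps24 was at 0.06. By limma 0 members were called over all genes or adjusted over the list alone, with 6 lower at an unadjusted p under 0.05. The call was lost with the processed signals (adjusted p = 0.256), without array 2 (0.0952) and with array 2 turned, where the mean was -0.0066 (0.920).

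Immediate early and heat shock genes fell as a list, with a mean log2 ratio of -1.63 over 18 genes (camera, adjusted p = 1.06e-05; adjusted p = 0.523 with an estimated correlation). The mean was -4.30 on array 1, -0.56 on array 2 and -0.05 on array 3. Atf3 had log2 ratios of -6.65, -0.27 and -0.95 and Egr1 -6.11, -1.91 and 0.19 on the 3 arrays. Control library 1 stood apart: its signal of Fos, a gene named after its values were seen, was 16.6 on the log2 scale, against 13.8 and 12.2 in the other controls and 10.1, 13.2 and 12.2 in the mutants. Without array 1 the list's mean was -0.30 (adjusted p = 0.0147; adjusted p = 0.785 with an estimated correlation). Called members numbered 0 over all genes and 0 adjusted over the list alone, with 3 lower at an unadjusted p under 0.05 by limma.

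**Figure D2:**
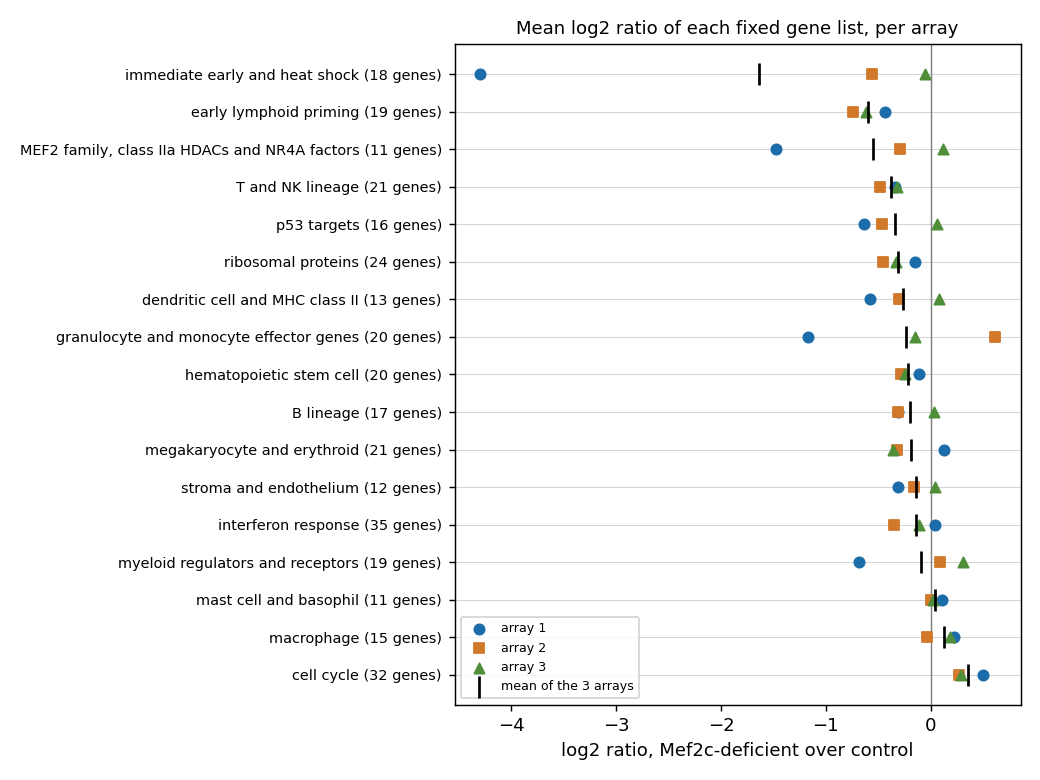
Mean log2 ratio of mutant over control (x axis) of the 17 gene lists (y axis) on each of the 3 arrays, with the mean as a bar. The early lymphoid list lies at -0.44, -0.74 and -0.62 and the cell cycle list at 0.50, 0.27 and 0.29, while the immediate early list reaches -4.30 on array 1 alone.

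Granulocyte and monocyte effector genes went both ways. Prtn3, a granule protease of early myeloid cells, had log2 ratios of 1.13, 1.26 and 0.70, and Elane, the neutrophil elastase gene, 0.60, 1.36 and 0.77, both named after their values were seen. Ngp and S100a9, genes of later neutrophils, had -4.33, 0.57 and -2.09 and -3.65, -0.12 and -2.04 on arrays 1, 2 and 3. Control library 1 had the highest Ngp signal, 14.5 on the log2 scale against 10.3 and 9.83 in the other controls. Adjusted over the list alone, Prtn3 was higher and Camp, a neutrophil granule peptide gene named after its values were seen, was lower (-2.887, -1.004 and -1.448), against 0 calls over all genes by limma, where 3 were higher and 2 lower at an unadjusted p under 0.05. The list did not pass (adjusted p = 0.677), and its mean of -0.24 and median of -0.000798 had the opposite sign to the test, which ran up. Its mean was -1.17, 0.61 and -0.14 on arrays 1, 2 and 3. Without array 1 the mean was 0.23 and the list passed upward (adjusted p = 0.0134), and without array 2 it was -0.66 and passed downward (0.0396). It also passed downward with array 2 turned, at -0.64 (adjusted p = 8.84e-05). These 3 calls were lost with an estimated correlation, where the adjusted p was 0.785, 0.796 and 0.969.

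Myeloid regulators and receptors did not pass (adjusted p = 0.397). Their mean of -0.09 was below 0 while their median of 0.20 and the test were above it. Egr1 and Egr2, which are also immediate early genes, had the largest ratios, -2.61 ± 3.21 and -1.19 ± 2.17 (SD, n = 3). This ranking rests mainly on array 1. On arrays 1, 2 and 3 Egr1 had -6.11, -1.91 and 0.19 and Egr2 had -3.69, -0.07 and 0.19, and without array 1 Egr2 was at 0.06. Without array 1 the list's mean was 0.20, with an adjusted p of 0.0399 (adjusted p = 0.785 with an estimated correlation).

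**Figure D3:**
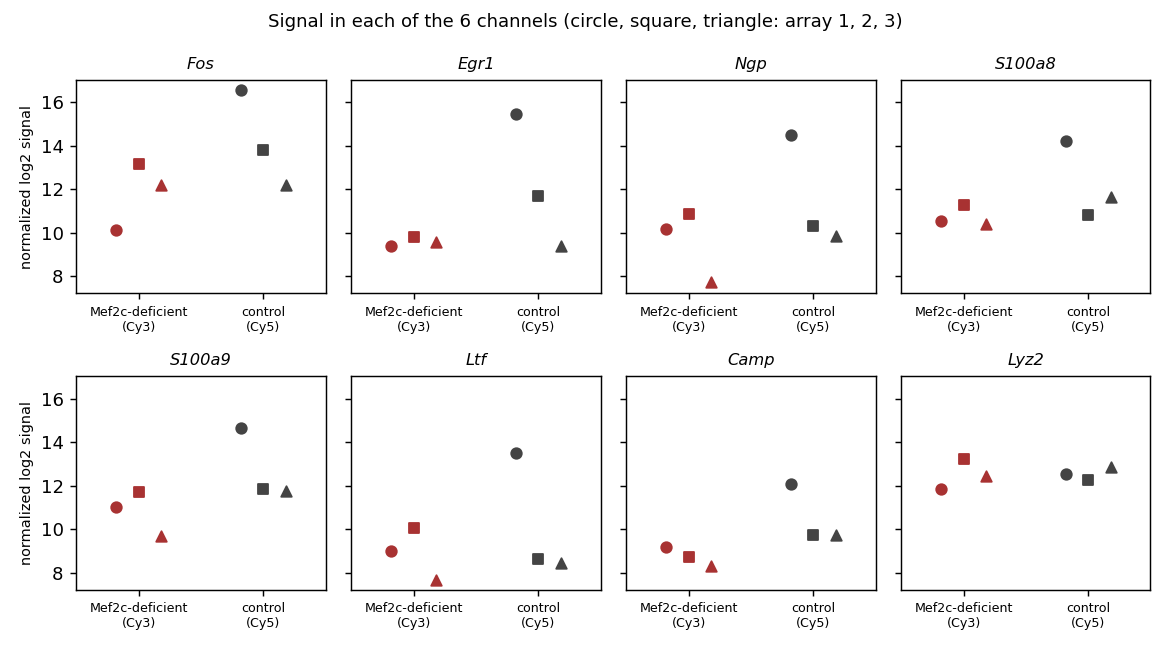
Normalized log2 signal (y axis) of 8 genes in the 3 mutant (Cy3) and 3 control (Cy5) channels (x axis), with a marker shape for each array. Control library 1 is highest for Fos (16.6), Egr1 (15.5), Ngp (14.5) and S100a8 (14.2), but not for Lyz2. Fos, S100a8, Ltf, Camp and Lyz2 were chosen after their values were seen.

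The remaining 9 lists did not pass. For hematopoietic stem cell genes the mean log2 ratio was -0.21 (adjusted p = 0.198), with Procr at -1.57 ± 0.91 and Hlf at -1.21 ± 0.71. Members went both ways, with 6 above 0 and 14 below, and 2 higher and 4 lower at an unadjusted p under 0.05 by limma. Megakaryocyte and erythroid genes had a mean of -0.18 (adjusted p = 0.259), with the hemoglobin gene Hba-a1 at -1.68 ± 1.03 and the red cell anion exchanger gene Slc4a1 at -1.32 ± 0.87. With array 2 turned Hba-a1 was at 0.02. The mean of interferon response genes was -0.14 (adjusted p = 0.259), with the chemokine gene Cxcl10 at -1.58 ± 1.66 and the RNA sensor gene Ifih1 at 1.28 ± 0.96. Cxcl10 had -3.49, -0.59 and -0.65 on arrays 1, 2 and 3. Among MEF2 relatives, class IIa HDACs and NR4A factors the mean was -0.55 (adjusted p = 0.198), with -1.48, -0.29 and 0.12 on the 3 arrays. Jun, at -1.76 ± 2.80, and Nr4a1, at -1.64 ± 2.97, are also immediate early genes. The p53 targets had a mean of -0.34 (adjusted p = 0.171), with Pmaip1 at -1.60 ± 2.28 and Trp53inp1 at -1.29 ± 0.87. Pmaip1 had -4.23, -0.27 and -0.29 on arrays 1, 2 and 3, and its signal in control library 1 was 14.6 against 10.2 and 10.7 in the other controls. With array 2 turned Trp53inp1 was at 0.05. By camera the p53 list passed without array 3 (adjusted p = 0.0454, and 0.689 with an estimated correlation) but not without array 1 (0.270). Without array 1 the stem cell list (-0.26, adjusted p = 0.0384), the megakaryocyte and erythroid list (-0.34, 0.00663) and the interferon list (-0.23, 0.0134) passed. These calls were lost with an estimated correlation, where the adjusted p was 0.679, 0.647 and 0.647.

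Markers of other cell types did not pass as lists. Macrophage genes, of cells that the sort against Mac-1 was meant to remove, had a mean log2 ratio of 0.12 (adjusted p = 0.304), with Adgre1 at 0.94, 1.23 and 0.84 on the 3 arrays. Axl was not well above background in any control and was at least 1.49-fold higher in the mutant (adjusted p = 0.461 by limma). This bound, open to dye bias, compares the mutants' mean signal with the lowest signal well above background in the controls, or the probe's own where higher. Dendritic cell and MHC class II genes had a mean of -0.26 (adjusted p = 0.259), with Cd74 at -1.10 ± 0.93 and Clec9a at -0.90 ± 1.73. Clec9a had -2.83, -0.39 and 0.52 on arrays 1, 2 and 3 and was well above background in 1 mutant and 2 control samples. By camera this list passed with the mean of each gene's probes (adjusted p = 0.0407, and 0.524 with an estimated correlation). Mast cell and basophil genes had a mean of 0.05, against a median of -0.03 (adjusted p = 0.677), with Ms4a2 at 0.56 ± 1.26 and Il4 at 0.31 ± 0.38. Stroma and endothelium genes had a mean of -0.14 (adjusted p = 0.304), with Col1a2 at 0.40 ± 0.23 and Pdgfra at -0.35 ± 0.49. By fry, 0 of the 17 lists had an adjusted p under 0.05, directional or mixed, and the early lymphoid list had 0.124 and 0.0525.

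The log2 ratios of the 3 arrays agreed in part. Across genes, which are not independent replicates, Pearson's r was 0.306 between arrays 1 and 2, 0.128 between arrays 1 and 3 and 0.0401 between arrays 2 and 3. Spearman's rho was 0.336, 0.155 and 0.0372. The mean r was 0.158, and it was -0.0727 with array 2 turned. A dye bias of single genes would also raise these correlations as labelled, so they do not settle the direction of array 2.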

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

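All tests in this part were chosen after the result they concern was seen. Camp, S100a8, Lyz2, Itgam, Cxcr2 and Fpr1 were named after their values were seen. Spots of a spike-in control sequence, used in no comparison, gave signal above the negative control spots in both channels. For the brightest spike-in probe the median Cy5 signal was 174.4, 141.4 and 159.9 times that of the negative spots on arrays 1, 2 and 3.

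Immediate early genes were far lower in the mutant on array 1. An effect of Mef2c loss of the same size in every pair is argued against by the list's mean of -0.30 on arrays 2 and 3 (-0.56 and -0.05), against -4.30 on array 1. Loess or background correction is argued against as the whole cause by a mean of -4.13 ± 0.40 (SE over members) on array 1 with neither background correction nor loess. What stays open is an effect that varies between pairs or an event in control library 1, which may include the handling of those cells: the median member lay 2.89 above the other controls, which share its dye, and 17 of 18 members were highest there among the 6 libraries. The mutant on that array differed from the other mutants by -0.63 in the median.

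Neutrophil genes were lower on array 1, by the mean of -1.76 over 19 measured markers of a list of 20. This list was written after such genes were seen, and 10 of its genes are in the granulocyte list and 2 in the myeloid regulator list. An effect of Mef2c loss of the same size in every pair is argued against by a mean of -0.090 ± 0.17 (SE over markers) on arrays 2 and 3, with 0.14 ± 0.19 on array 2 and -0.32 ± 0.23 on array 3. An effect that varies between pairs stays open, since Ngp (-2.09), S100a9 (-2.04), Camp (-1.45) and S100a8 (-1.22) were also lower on array 3. Camp, S100a9, Itgam, Cxcr2 and Fpr1 were lower on all 3 arrays, with Itgam at -1.28, -1.05 and -0.83. Of the 19 markers, 8 lay below 0 on array 2 and 9 on array 3. A candidate source is neutrophil RNA in control preparation 1, although the sort used Gr-1 and Mac-1 to remove such cells: the median marker lay 1.43 above the other controls and 17 of 19 lay above, while Lyz2, abundant in neutrophils but also high in the other libraries, was 12.6 on the log2 scale against 12.3 and 12.9. A difference in the gated progenitors of that control was not tested.

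Early lymphoid genes were lower on all 3 arrays. Array 1 alone is argued against by a mean of -0.68 without it. Dye bias of single probes as the whole cause is argued against, for 9 list genes with other probes, by those probes' mean of -0.56. The tested probes of these genes had -0.69 (6 of 9 below 0 in the other probes, exact 1-sided sign-flip p = 0.0156). Dntt at -2.21 and Ets1 at -1.20 weigh most in that mean, and the p treats genes as independent. Flt3 and Ikzf1 had 1 probe each, so single-probe dye bias stays open for them. A dye effect shared by all probes of a transcript cannot be excluded, since the labels give no dye swap, and turning array 2 ended the call (mean -0.11). Mef2c loss, which cannot be told apart from the presence of Cre, stays open, as does a different share of lymphoid-primed cells in the gate.

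The 3 ratios allow 4 sign splits, too few for a share under 0.05. Here the real split is the labelled one, and the split that turns array 2 may instead be the true direction. A dye bias shared by the arrays would also set the labelled split apart, so these counts cannot measure chance. For genes at an adjusted p under 0.05, 4 of 4 splits gave as many as the real count of 0 by limma, and the highest other gave 0. At an unadjusted p under 0.05 the real count was 2251 and the highest other 1356, so 1 of 4 was as large. For lists called the real count was 5 and the highest other 7, so 2 of 4 were as large.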

How the results depend on the processing

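Turning array 2, using the deposited signs and leaving out background correction and loess together were chosen after seeing the data. By limma the count of genes at an adjusted p under 0.05 was 0 under every alternative that used it, including a false discovery rate of 0.10, a 2-fold minimum and single probes, and it was 2251 without adjustment. Median centring moved the median of all genes by -0.13 on the log2 scale and gave 552 higher and 2318 lower genes at an unadjusted p under 0.05, and with processed signals 695 were higher. With array 2 turned 335 were higher and 308 lower, and with the deposited signs 341 and 309. Without background correction and loess there were 797 and 1657. The cause was not tested. Leaving out 1 array gave 638 to 1354 higher, 662 to 1376 lower and 5 to 10 lists called.

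The number of lists called was 5, and 3 with array 2 turned or with the deposited signs. It was 0 with an estimated correlation, also when 1 array was left out, with array 2 turned, with the deposited signs and with the mean of each gene's probes, and 0 with fry, directional or mixed. These combined settings were added after seeing the data, and leaving out 1 array leaves 1 residual degree of freedom for that estimate. With an estimated correlation the test's own degrees of freedom also come from the arrays, so with this few it has little power. For the early lymphoid list that correlation was -0.0281, below the preset 0.01, yet camera's unadjusted p went from 7.97e-05 to 0.0504. A higher correlation thus cannot account for the loss of that call. For immediate early genes the estimated correlation was 0.928, and for the other lists the cause was not tested. The cell cycle and immediate early lists were called under all 19 processing alternatives, with means of 0.17 to 0.39 and of -2.43 to -0.30. The early lymphoid and T and NK lists were called under 17, all but the turned array 2 and the deposited signs. The granulocyte list's test turned downward and passed without array 2 (mean -0.66, adjusted p = 0.0396, against 0.23 upward without array 1), with array 2 turned (-0.64, adjusted p = 8.84e-05) and with the deposited signs (-0.66, adjusted p = 9.56e-05), and that of ribosomal proteins upward with array 2 turned (-0.0066) and the deposited signs (-0.0090). With array 2 turned or the deposited signs, the B lineage, megakaryocyte and erythroid, interferon and p53 tests also turned upward. That of myeloid regulators turned downward, and none of these passed. The cause of these turns was not tested.

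Mef2c stayed uncalled, from -0.44 to 0.13, and leaving out 1 array gave -0.44 to 0.09. The unpaired fit of channels, with no replicate block, gave 0 genes, 1118 higher and 1498 lower at an unadjusted p, 5 lists and a Mef2c ratio of -0.26. Mean agreement of the arrays was -0.0727 with array 2 turned. Aquantile left each probe's ratio as it was and changed the probe of 3 genes. Of 68 other genes followed, 41 of them named by the rule, 11 changed sign in at least 1 alternative and 0 were called in any. A slide block was not run, since 1 slide held all arrays. Signal over background left 489 genes well above it in 1 of the groups only, so their ratios are bounds.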

Other observations

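The families in this part, and the genes named from them apart from F10, were chosen after values were seen, so no test of them is given. Gimap genes, GTPases of lymphocytes, had a mean log2 ratio of -0.67 over 7 genes, with -0.68, -0.83 and -0.48 on arrays 1, 2 and 3, and 5 of 7 ran low on all 3 arrays. Gimap1 was at -1.37 ± 0.42 and Gimap7 at -0.99 ± 0.36 (SD, n = 3). MHC class I genes had a mean of -0.49 over 16 genes, with 11 low on all 3 arrays, among them H2-T23 at -0.87 ± 0.09 and H2-K1 at -0.71 ± 0.39. Near-identical class I copies can share a probe, so these are not 16 separate measurements.

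Coagulation factor genes had a mean log2 ratio of 0.60 over 8 genes, with a median of 0.39 and with 0.67, 0.58 and 0.55 on arrays 1, 2 and 3. Of these 8 genes 4 ran high on all 3 arrays and 0 ran low on all 3. The rest had means between -0.22 and 0.06, so the family's mean came from those 4. F10 was at 1.71 ± 0.37, F7 at 1.63 ± 0.50 (SD, n = 3), and F13a1 at 0.41, 1.05 and 1.54 on the 3 arrays. Ms4a genes had a mean of 0.31 over 13, of which 6 ran high and 2 ran low on all 3 arrays, with Ms4a4c at 0.55 ± 0.06. The means of the 4 families kept their sign under the processing alternatives, from -0.87 to -0.11 for Gimap, -0.68 to -0.19 for MHC class I, 0.22 to 0.62 for coagulation factors and 0.06 to 0.42 for Ms4a. Turning array 2 gave -0.11, -0.19, 0.22 and 0.06, and the counts of genes that run the same way on all 3 arrays hold only for the labelled direction.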
